A study of Homo sapiens with 8 samples.

How the data were processed

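The data are RMA expression values of 8 Affymetrix arrays of human MDA-MB-231 breast cancer cells with a control hairpin, 4 untreated and 4 treated with TGFβ. Per the labels' protocols, total RNA was taken with Trizol and biotinylated cRNA was made with a transcript labelling kit. The deposited table holds 1 log2 value per probe set and array. The values were made by the authors with RMA, per the submitters' processing notes, which corrects background, normalizes between arrays and summarises the probes of a probe set. The version of RMA, and which arrays were normalized together, are not given in the sources used here. That the scale is log2 was inferred from RMA and from values that stay under 14 on nearly equal distributions; no header states the base. RMA gives no detection calls, so a low signal cannot be told from background, and RMA values of probe sets that lie close to background understate changes.

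Of 54675 probe sets 62 are Affymetrix controls, which left 54613. Genes were named through GEO's platform annotation of 2016, where 41091 of the tested probe sets name 1 gene, 1801 several and 11721 none; only the first were used for genes. For 41037 of the 41091 the Entrez identifier was found in the RefSeq table, and no symbol changed. This gave 19777 genes, 10523 of them with more than 1 probe set; the probe set with the highest mean over all 8 arrays stood for its gene. Probe sets of 1 gene can disagree, and the number in the direction of the gene is given where they did so for a gene with a fold change in the results. No genome build is given in the sources used here, and no coordinates are printed.

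Groups came from the labels. The 2 groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior, treated minus untreated, two-sided), with Benjamini-Hochberg adjustment over the genes or probe sets tested and a threshold of 0.05. Gene lists, 37 with 724 symbols, were tested with camera at a preset correlation of 0.01, adjusted over the 37 lists; 661 symbols matched directly, 2 through an older symbol, and 61 named no measured gene. Members of a list were counted both over all genes and adjusted over the list alone. Array checks used exact permutation tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

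Both groups carry the letters A to D, and the labels call the samples biological replicates without saying what a letter stands for or whether cultures were separate. The correlation of the deviations from the group means over genes was 0.49, 0.69, 0.34 and 0.30 for the same-letter arrays of A, B, C and D. Between letters the median was -0.22, but deviations from a group mean cancel out, so positive same-letter values by themselves make the others negative. For 6 of the 8 arrays the best match in the other group had the same letter. The letters thus pair the arrays incompletely, and this pairing is taken from the data and not from the labels. The fit without the letter is the one reported, and the fit with the letter as a replicate block (705 genes in place of 114) is given beside the calls and counts of the results that it changes most.

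Lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. The rule takes the 12 largest increases and 12 largest decreases at an adjusted p of 0.05 with no overlap between groups, a set of fixed genes (SMAD7, SKIL, ID1, BHLHE41, CCNG2, ADAMTS9, FST and 2 more that are not analysed here), and from each list the 4 members with the smallest p, or 2 where no member passed. It names 122 genes, not all of which are mentioned. Alternatives were the replicate block, only the upper 60% of signals, centring on the array median, quantile normalization again, a trended and robust prior, the mean of a gene's probe sets, leaving out probe sets that can match several transcripts, each array left out in turn, camera with an estimated correlation, and fry. Added after seeing the data were the block fit without each letter, camera with an estimated correlation in the block fit, and gene families (p adjusted over the 4 tested, of which 3 are described). All 35 splits of the 8 arrays into 4 and 4 were refitted.

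The fits were tested on simulated data with 200 changed genes among 19777 on independent arrays. The fit without the block recovered 54% of the genes changed 1.5-fold and 86% of those changed 2-fold, with 8 false among 148 calls, and the block fit 20% and 70%, with 6 false among 96. In a simulation with shared letter effects the block fit recovered 52% and 87%, with 2 false among 141 calls, and the fit without the block 48% and 84%, with 0 false among 132. Of 100 simulated lists without a shift, 2 had a camera p under 0.05. Genes were drawn independently there, so this does not test camera on lists whose genes move together. Arrays of p53-depleted cells were not analysed here.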

Results

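Expression was measured in MDA-MB-231 cells, a line from a metastatic human breast cancer, that carried a hairpin RNA against GFP as a control. The cells went without serum for 24 h and were then left untreated or given TGFβ, a cytokine that signals through SMAD transcription factors. The labels give a dose of 5 µg/ml for 3 h. TGFβ is usually given in ng/ml, so the unit is uncertain. Each group had 4 arrays with the replicate letters A to D, and all 8 entered the comparison. The series asks which genes are under the joint control of TGFβ and mutant p53. Its arrays of p53-depleted cells were not analysed here, so only the response of the control cells to TGFβ is described. The number of arrays limits the precision, and the p-values measure the spread between these arrays only. Values are RMA log2 signals per probe set, with 1 probe set for each of 19777 genes, and the median signal of an array lay between 4.63 and 4.66.

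After TGFβ, EDN1 (Entrez Gene 1906), which encodes the vasoconstrictor peptide endothelin, rose most among the genes that passed the test. Its signal went from 7.46 ± 0.14 to 10.26 ± 0.60 (log2, SD, n = 4 in each group), a 6.96-fold increase (log2 fold change 2.80 ± 0.24 SE, adjusted p = 0.000737). ANGPTL4 (51129), a secreted inhibitor of lipoprotein lipase, rose 5.21-fold (2.38 ± 0.18 SE, adjusted p = 0.000392). VGLL3 (389136), a cofactor of TEAD transcription factors, rose 4.05-fold (2.02 ± 0.20 SE, adjusted p = 0.00146), and NEDD9 (4739), a scaffold protein of focal adhesions, 3.90-fold (1.96 ± 0.26 SE, adjusted p = 0.00774; 4 of its 5 probe sets in that direction). COL1A1 (1277), a chain of fibrillar collagen, rose 3.23-fold (1.69 ± 0.17 SE, adjusted p = 0.00179), and the transcription factor JUNB (3726) 3.11-fold (1.64 ± 0.11 SE, adjusted p = 0.000168). The other genes among the 12 largest increases were PMEPA1 (log2 fold change 2.24), RASGRP1 (1.94), SGK1 (1.83), SMAD7 (1.81), TGFBI (1.56) and DDB2 (1.46). PMEPA1, RASGRP1, SGK1 and DDB2 lost the call when some arrays were left out. They passed in 3, 2, 2 and 2 of the 8 such fits, with adjusted p up to 0.148, 0.0889, 0.116 and 0.115. The other 8 passed whichever array was left out. These fits ignore the letters. With the letter as a block PMEPA1, RASGRP1, SGK1 and DDB2 had adjusted p of 0.0005, 0.00048, 6.47e-06 and 0.000233.

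SPRY1 (10252), an inhibitor of receptor tyrosine kinase signalling, fell most among the genes that passed the test, from 8.45 ± 0.20 to 6.72 ± 0.40 (log2, SD, n = 4 in each group; log2 fold change -1.73 ± 0.18 SE, adjusted p = 0.0021). PDK4 (5166), a kinase that inhibits pyruvate dehydrogenase, had a log2 fold change of -1.66 ± 0.25 SE (adjusted p = 0.016). BMP4 (652), a ligand of the bone morphogenetic protein branch of the TGFβ family, had -1.39 ± 0.22 SE (adjusted p = 0.0218). PTCH1 (5727), the receptor for hedgehog ligands, had -1.24 ± 0.15 SE (adjusted p = 0.00379), but only 3 of its 5 probe sets had that direction. IFIT2 (3433), an interferon-induced gene, had -1.16 ± 0.12 SE (adjusted p = 0.00182). NR3C2, the mineralocorticoid receptor, had -1.08 ± 0.13 SE (adjusted p = 0.00447). LGALSL (-1.49), PARD6B (-1.42, with 2 of its 3 probe sets in that direction), PDE4B (-1.35), PAG1 (-1.32), ABHD17C (-1.13) and TMCC3 (-1.07) complete the 12 largest decreases. PDK4, LGALSL, PARD6B, BMP4 and PAG1 passed in 5, 1, 3, 5 and 1 of the 8 fits without 1 array, with adjusted p up to 0.0755, 0.145, 0.0909, 0.106 and 0.106, and the other 7 passed in all. With the letter as a block, which these fits lack, PDK4, LGALSL, PARD6B, BMP4 and PAG1 had adjusted p of 0.000448, 2.36e-05, 0.00172, 2.45e-05 and 0.00355.

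**Figure D1:**
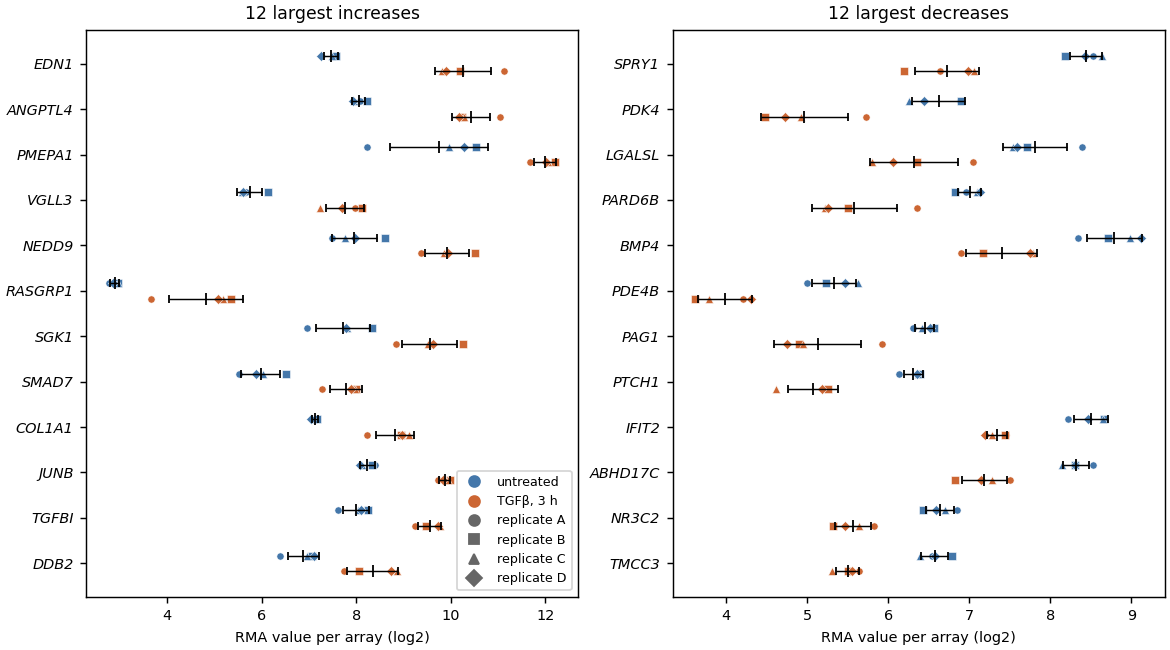
RMA log2 signal on each array for the 12 genes that rose most and the 12 that fell most after TGFβ, among those that passed the test. Points are arrays, coloured by group with a marker per replicate letter, and black bars are means with SD (n = 4 in each group). The groups do not overlap for any of these genes, and treated replicate A lies apart from the other treated arrays for RASGRP1 (3.66) and ANGPTL4 (11.03).

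In all, 114 genes changed, 70 of them up and 44 down, and 112 of these differed by at least 1.5-fold. At least 2-fold changes were seen in 42 genes that rose and 16 that fell. Over probe sets, 140 of 54613 passed, 83 up and 57 down. In each of the 114 genes the groups did not overlap, which by itself gives the same direction in all 4 same-letter pairs. Over all genes, 5.12% had groups without overlap, where chance gives 2.86% if the arrays can be exchanged, which their pairing by letter makes uncertain. Arrays of the same letter shared deviations, and with the letter as a block 705 genes passed, 274 up and 431 down. All 114 genes were among them with the same direction. The counts of genes changed at least 1.5-fold and of probe sets were 313 and 954 in that fit. The count depended on single arrays: it was 49 without untreated replicate C, 53 without untreated replicate D, 59 without treated replicate C, 46 without treated replicate D and 232 without treated replicate A. A set of 42 genes passed whichever array was left out, 29 higher and 13 lower. Splitting the same arrays by letter, A and B against C and D, gave 192 genes.

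The list of genes known as early targets of SMAD proteins was called higher. TGFBI, an extracellular matrix protein, rose 2.95-fold (1.56 ± 0.16 SE, adjusted p = 0.00179). SMAD7, the inhibitory SMAD of the pathway's own feedback, rose as well (1.81 ± 0.21 SE, adjusted p = 0.0039). The repressor BHLHE40 rose by 1.21 ± 0.18 SE (log2, adjusted p = 0.0162) and the matricellular protein CCN2 by 0.62 ± 0.09 SE (adjusted p = 0.0178). Of 17 measured targets 5 rose, none fell and 12 did not pass. Adjusted over the list alone 10 rose and 1 fell, and 9 rose and 1 fell in the fit with the letter as a block. Their mean was 0.58, between 0.45 and 0.66 in the 4 same-letter pairs, and limma's camera with a preset correlation called the list higher (adjusted p = 3.58e-08; adjusted p = 0.138 with an estimated correlation). SKIL, another feedback regulator, had a log2 fold change of 1.41 ± 0.35 SE that did not pass (adjusted p = 0.157; 0.00205 with the block). ID1, an inhibitor of basic helix-loop-helix factors, had 0.50 ± 0.17 SE (adjusted p = 0.405; 0.0595 with the block). BHLHE40 and CCN2 passed in 5 and 4 of the 8 fits without 1 array, with adjusted p up to 0.0828 and 0.0889 without untreated replicate C.

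Components of the TGFβ pathway itself went both ways. FSTL3, a secreted antagonist of activins, rose 2.27-fold (1.18 ± 0.10 SE, adjusted p = 0.000737), whereas INHBB, an activin subunit, had a log2 fold change of -1.03 ± 0.14 SE (adjusted p = 0.00919) and BMP4 fell as given above. The co-receptor TGFBR3 had -1.12 ± 0.29 SE and did not pass (adjusted p = 0.164; 0.000541 with the block). Of 29 ligands, receptors and SMADs 1 rose, 2 fell and 26 did not pass, or 1 and 6 when adjusted over the list alone, and the list as a whole was not called (adjusted p = 0.486). With the block 1 rose and 5 fell.

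The lists of extracellular matrix and actin cytoskeleton genes were called higher, though few of their genes passed. Of 30 matrix and collagen genes 2 rose, COL1A1 and COL4A1, a chain of basement membrane collagen (1.28 ± 0.22 SE, adjusted p = 0.0271), and 28 did not pass. The count was 6 up and 1 down when adjusted over the list alone, and 8 up and 2 down over all genes with the block. The list mean was 0.26 (adjusted p = 0.000202; adjusted p = 0.138 with an estimated correlation). THBS1, a matricellular activator of latent TGFβ, had 1.20 ± 0.26 SE (adjusted p = 0.0884; 0.000117 with the block). Of 21 actin cytoskeleton genes 3 rose and 18 did not pass, with 4 up when adjusted over the list alone. They were TUFT1 (1.41 ± 0.09 SE, adjusted p = 0.000168), the actin-binding tropomyosin TPM1 (0.60 ± 0.08 SE, adjusted p = 0.011) and the small GTPase RHOB (1.03 ± 0.15 SE, adjusted p = 0.0139; 3 of its 5 probe sets in that direction). The mean of the 21 genes was 0.21 (adjusted p = 0.00141; adjusted p = 0.138 with an estimated correlation), but their median was only 0.08. Of 24 matrix proteases and crosslinking enzymes 1 rose, the metalloprotease ADAM19 (1.30 ± 0.22 SE, adjusted p = 0.0263; 1 of its 2 probe sets in that direction), and 3 when adjusted over the list alone or with the block. That list had a mean of 0.17 (adjusted p = 0.0404; adjusted p = 0.292 with an estimated correlation). It lost its call without untreated replicate A (adjusted p = 0.11), untreated replicate C (0.188) or treated replicate B (0.284), and with the upper 60% of signals (0.0624) or the mean of a gene's probe sets (0.086). COL4A1, TPM1, RHOB and ADAM19 passed in 2, 6, 5 and 2 of the 8 fits without 1 array, with adjusted p up to 0.123, 0.0568, 0.0727 and 0.122.

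Growth factors and immediate early genes included members that rose and members that fell. PDGFB, a platelet-derived growth factor chain, rose 2.23-fold (1.16 ± 0.10 SE, adjusted p = 0.000737) and HBEGF, a ligand of the EGF receptor, 2.14-fold (1.10 ± 0.19 SE, adjusted p = 0.0296; 3 of its 4 probe sets in that direction), while CSF1, the macrophage colony-stimulating factor, had a log2 fold change of -1.04 ± 0.13 SE (adjusted p = 0.0062). Of 20 growth factors, cytokines and receptors such as EGFR and MET 2 rose, 1 fell and 17 did not pass. The counts were 6 and 1 when adjusted over the list alone and 5 and 2 with the block. As a group they had a mean of 0.26 (adjusted p = 0.000166; adjusted p = 0.223 with an estimated correlation). Without probe sets that can match several transcripts it was 0.16 and did not pass (adjusted p = 0.06). Of 22 immediate early genes 2 rose, JUNB and JUN (0.84 ± 0.12 SE, adjusted p = 0.0102), 1 fell, FOSL2 (-1.03 ± 0.16 SE, adjusted p = 0.0172), and 19 did not pass. Adjusted over the list alone 2 rose and 2 fell, and with the block 4 rose and 1 fell. The mean of 0.23 passed (adjusted p = 0.00445; adjusted p = 0.335 with an estimated correlation) but not without treated replicate B (adjusted p = 0.0991). HBEGF, JUN and FOSL2 passed in 3, 5 and 5 of the 8 fits without 1 array, with adjusted p up to 0.126, 0.0564 and 0.0775.

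The bone metastasis genes and the YAP and TEAD targets were called higher, and the lung metastasis genes were not. Of 11 bone metastasis genes CCN2 rose, RUNX2, a transcription factor of bone, fell (-0.60 ± 0.11 SE, adjusted p = 0.0476; 3 of its 6 probe sets in that direction), and 9 did not pass. The counts were 5 and 1 when adjusted over the list alone and 4 and 1 with the block. The cytokine IL11 had 1.46 ± 0.39 SE (adjusted p = 0.191; 2.13e-05 with the block) and JAG1, a Notch ligand, 0.72 ± 0.18 SE (adjusted p = 0.154; 0.00119 with the block). The list mean was 0.39 (adjusted p = 0.00666; adjusted p = 0.231 with an estimated correlation), and the call was lost without treated replicate B (adjusted p = 0.081). Of 17 lung metastasis genes 2 rose, ANGPTL4 and NEDD9, also when adjusted over the list alone. The list had a mean of 0.27 and was not called (adjusted p = 0.0567), but passed with the block (adjusted p = 0.0342; 0.275 with the block and an estimated correlation), with the upper 60% of signals (0.0119), with centring (0.0454) and with quantile normalization again (0.0444). With the block 2 of its genes rose and 1 fell. Of 22 YAP and TEAD targets 2 rose, CCN2 and the stress-response gene GADD45B (1.03 ± 0.13 SE, adjusted p = 0.00583), 20 did not pass, and 3 rose when adjusted over the list alone or with the block. The mean was 0.18 (adjusted p = 0.0404; adjusted p = 0.735 with an estimated correlation). It was 0.05 without treated replicate A (adjusted p = 0.514), the array with the 3-prime excess described below, and the call was also lost without untreated replicate C (0.274), untreated replicate D (0.105) or treated replicate B (0.309), and without probe sets that can match several transcripts (0.0805). RUNX2 passed in 1 of the 8 fits without 1 array (adjusted p up to 0.183).

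The lists of MAP kinase feedback genes and of FOXO and starvation targets were called lower, though few of their genes passed. Of 14 MAP kinase feedback genes 2 fell, SPRY1 and SPRED2 (-0.80 ± 0.11 SE, adjusted p = 0.0102), none rose and 12 did not pass. Adjusted over the list alone 2 rose and 4 fell, as with the block. DUSP4 and DUSP7, phosphatases of MAP kinases, lay on opposite sides, at -0.53 ± 0.11 SE (adjusted p = 0.08; 0.0201 with the block) and 0.49 ± 0.11 SE (adjusted p = 0.0892; 0.0311 with the block). With a mean of -0.27 the list was called (adjusted p = 0.00304; adjusted p = 0.159 with an estimated correlation), and without treated replicate A it did not pass (-0.24, adjusted p = 0.0652). Of 22 genes induced by FOXO or starvation 2 fell, PDK4 and the receptor tyrosine kinase ERBB3 (-0.96 ± 0.15 SE, adjusted p = 0.0206; 2 of its 5 probe sets in that direction), and 20 did not pass. Adjusted over the list alone 5 fell, and with the block 6 fell and 1 rose. CITED2, a transcriptional coregulator, had -0.95 ± 0.22 SE (adjusted p = 0.121, and 0.000216 with the block), with 2 of its 3 probe sets in that direction. TRIB2, a pseudokinase, passed with the block only (adjusted p = 0.243 and 0.000448). The list mean was -0.30 (adjusted p = 0.00044; adjusted p = 0.138 with an estimated correlation). SPRED2 and ERBB3 passed in 6 and 5 of the 8 fits without 1 array, with adjusted p up to 0.0529 and 0.0775.

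The list of interferon-response genes was called lower. IFIT2, IFIT1 and IFIT3, which encode antiviral RNA-binding proteins, fell, with log2 fold changes of -1.16 ± 0.12, -0.69 ± 0.11 and -0.71 ± 0.12 (SE; adjusted p = 0.00182, 0.0178 and 0.0263), in 4 of 4 same-letter pairs each. RIGI, a sensor of viral RNA, had -0.51 ± 0.13 SE (adjusted p = 0.157; 0.0081 with the block). Of 21 measured genes 3 fell, none rose and 18 did not pass, 16 had a negative log2 fold change, and 5 fell when adjusted over the list alone. The list mean was -0.23, between -0.27 and -0.20 in the 4 pairs (adjusted p = 1.18e-05; adjusted p = 0.138 with an estimated correlation). Its median was -0.11, and 12 of the 21 genes were lower in pair C, against 17 in each of the other pairs. IFIT1 and IFIT3 passed in 4 and 3 of the 8 fits without 1 array, with adjusted p up to 0.0889 and 0.111 without untreated replicate C.

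Cell cycle genes gave list calls without a single gene that passed. Of 28 genes of mitosis 27 had a negative log2 fold change, with a mean of -0.24 (adjusted p = 0.000145; adjusted p = 0.64 with an estimated correlation). None passed over all genes or when adjusted over the list alone. With the block 1 fell over all genes and 10 when adjusted over the list alone. ASPM, a spindle protein, had -0.66 ± 0.21 SE (adjusted p = 0.296; 0.0286 with the block) and the kinetochore motor CENPE -0.54 ± 0.22 SE (adjusted p = 0.527). Both arrays of letter B had lower levels of this list than the others, at 8.33 against 9.07 to 9.12 untreated and 8.19 against 8.79 to 8.86 treated, and without treated replicate B, which leaves untreated B without its partner, the mean was -0.08 (adjusted p = 0.1). Without untreated replicate B the mean of the mitosis list was -0.43. Within the letters the mean was negative in all 4 pairs, from -0.33 to -0.14 (adjusted p = 2.09e-09 with the block; 0.147 with the block and an estimated correlation). Of 27 genes of DNA replication 24 had a negative value and none passed, also when adjusted over the list alone. The mean of -0.12 (adjusted p = 0.0124; adjusted p = 0.781 with an estimated correlation) changed sign without treated replicate B (0.03, adjusted p = 0.997) and was above 0 in 1 of the 4 pairs. It did not pass without untreated replicate C (0.214) or untreated replicate D (0.146), with the upper 60% of signals (0.0914) or without probe sets that can match several transcripts (0.0553). The CDK inhibitors CDKN1A and CDKN1B went in opposite directions, with 1.13 ± 0.14 SE and -0.70 ± 0.09 SE (adjusted p = 0.0062 and 0.00617). Their list of 10 cell cycle regulators was not called (adjusted p = 0.174; 0.038 without probe sets that can match several transcripts). It had the same 1 up and 1 down when adjusted over the list alone, and 1 up and 2 down with the block. The list mixes CDK inhibitors with CCND1, CDC25A and MYC, so a test for 1 direction does not measure growth arrest.

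**Figure D2:**
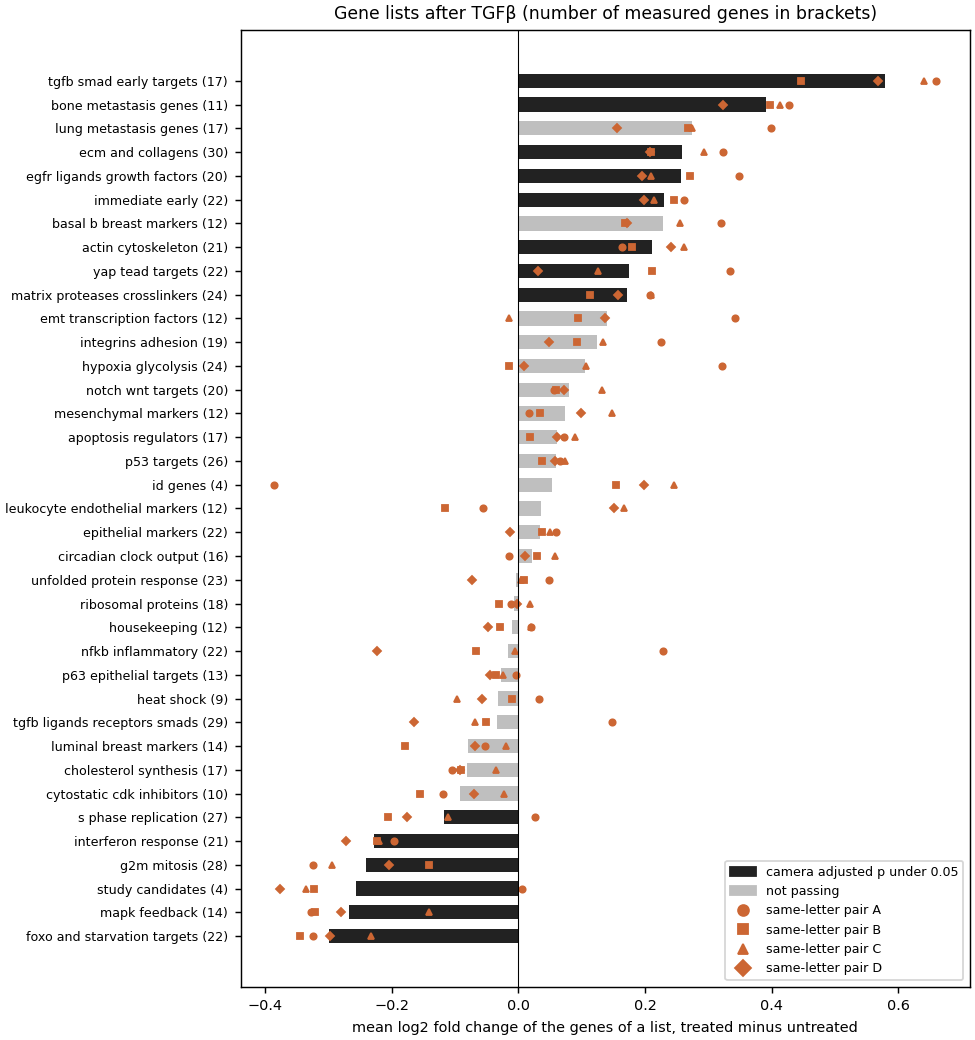
Mean log2 fold change (treated minus untreated) of the genes of each of the 37 lists, with the number of measured genes in brackets. Black bars passed camera with the preset correlation, grey bars did not, and markers give the mean of each same-letter pair; the early SMAD targets have the highest mean (0.58) and the FOXO and starvation list the lowest (-0.30).

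Over the 37 lists, 8 were called higher and 6 lower with the preset correlation, and none with an estimated correlation (limma's camera; smallest adjusted p 0.138, 7 lists at an unadjusted p under 0.05). By fry, which asks whether the genes of a list move on balance 1 way, 8 lists passed, 7 of the 14 and the lung metastasis list. With the letter as a block 19 lists passed by fry. The 6 lists called lower, and the 7 that passed by fry without the block, include the genes for which the study is known. Its authors chose those genes on arrays of this series, so that call is not independent evidence. Without treated replicate B 9 lists passed, and another split of the 8 arrays into 4 and 4 gave 15 lists. Among the lists not called, SNAI2, a repressor of epithelial genes, rose (0.96 ± 0.12 SE, adjusted p = 0.0062) as 1 of 12 transcription factors of the epithelial-mesenchymal transition (list adjusted p = 0.0638, and 0.0169 without probe sets that can match several transcripts; 2 up when adjusted over the list alone). CDH1, the epithelial cadherin, rose as well (0.90 ± 0.11 SE, adjusted p = 0.00579), at a low signal of 4.08 to 4.98, as 1 of 22 epithelial genes (list adjusted p = 0.79; 2 up when adjusted over the list alone, and 2 up and 2 down with the block; the list mean is above 0 and its median below). Of 12 mesenchymal markers none passed (list adjusted p = 0.79; 1 up and 1 down when adjusted over the list alone or with the block). TAGLN, an actin-binding protein, had 0.93 ± 0.20 SE (adjusted p = 0.101; 0.000447 with the block).

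Among 20 Notch and Wnt genes the ligand WNT5B rose (1.01 ± 0.16 SE, adjusted p = 0.023) and the receptor FZD7 fell (-0.66 ± 0.12 SE, adjusted p = 0.0422), with 3 up and 1 down when adjusted over the list alone and 4 and 1 with the block (list adjusted p = 0.486). They passed in 1 and 2 of the 8 fits without 1 array, with adjusted p up to 0.0959 and 0.175. Of 24 hypoxia and glycolysis genes ANGPTL4 and PFKFB3, an activator of glycolysis, rose (PFKFB3 0.72 ± 0.12 SE, adjusted p = 0.0218; passing in 3 of the 8 fits, adjusted p up to 0.106), 4 up and 1 down when adjusted over the list alone and 4 up with the block (list adjusted p = 0.509; mean above 0 and median below). Of 26 p53 targets CDKN1A and DDB2 rose and 24 did not pass, 4 up and 2 down when adjusted over the list alone and 3 and 3 with the block (list adjusted p = 0.79). Of 13 p63 targets in epithelia 1 fell, BHLHE41, 1 up and 1 down when adjusted over the list alone and 1 and 2 with the block (list adjusted p = 0.662; mean below 0 and median above). Of 16 genes of the circadian clock and its output BHLHE40 rose and BHLHE41 fell, 2 and 2 when adjusted over the list alone or with the block (list adjusted p = 0.791; mean above 0, test in the other direction). Of 17 apoptosis genes GADD45B rose, also when adjusted over the list alone, and 2 rose and 1 fell with the block (list adjusted p = 0.741). Of 19 integrin and adhesion genes NEDD9 rose, 2 up over the list alone and 2 up and 1 down with the block (list adjusted p = 0.177). Of 12 basal breast markers TGFBI rose, 2 up over the list alone or with the block (list adjusted p = 0.114, and 0.0496 with the upper 60% of signals).

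No gene passed over all genes or when adjusted over the list alone in the lists of cholesterol synthesis (17 genes, list adjusted p = 0.0567), heat shock (9, 0.668), ID genes (4, 0.779), NF-κB and inflammation (22, 0.87; mean and median below 0, test above), ribosomal proteins (18, 0.79), housekeeping (12, 0.79) or the unfolded protein response (23, 0.91; mean below 0, median above). With the block 1 gene, IL1A, rose in the NF-κB list (0.72, adjusted p = 0.015, 1 of its 2 probe sets in that direction) and 1, ERN1, a sensor of unfolded proteins, fell in that of the unfolded protein response (-0.44 ± 0.19 SE, adjusted p = 0.0337, 2 of its 3). In cholesterol synthesis 15 of 17 genes had a negative value, with a mean of -0.08. The lists of markers of cells that the culture should not hold were not called, though the groups did not overlap for PECAM1, TEK or ERBB3. These tests compare the groups and do not show whether such transcripts were absent. The mean signal per array was 7.83 to 8.06 for the luminal list and 4.70 to 4.86 for the leukocyte and endothelial list. Array medians over all probe sets were 4.63 to 4.66. Of 12 leukocyte and endothelial genes none passed, and 1, PECAM1, was lower when adjusted over the list alone (-0.43 ± 0.12 SE, adjusted p = 0.207; 0.0155 with the block, 4 of its 5 probe sets in that direction, list adjusted p = 0.791). Of 14 luminal breast markers 1 fell, ERBB3, also when adjusted over the list alone (list adjusted p = 0.486).

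The genes for which the study is known were examined on their own. Its authors chose them on arrays of this series, so their direction here is not independent evidence. BHLHE41, a circadian repressor also called SHARP1, fell (-0.76 ± 0.10 SE, adjusted p = 0.00774), from 6.41 ± 0.12 to 5.65 ± 0.13 (SD, n = 4 in each group), whichever array was left out. Of its 4 probe sets 1 passed and 3 had that direction. The mean of all 4 gave -0.23 (adjusted p = 0.315), and without probe sets that can match several transcripts BHLHE41 had -0.03 (adjusted p = 0.972). CCNG2, an atypical cyclin, had -0.42 ± 0.16 SE (adjusted p = 0.505) and passed with the block (0.0222), with 4 of its 5 probe sets in that direction. ADAMTS9, a secreted metalloprotease, had -0.49 ± 0.17 SE (adjusted p = 0.422; 0.0316 with the block; 0.0259 without treated replicate A), with 2 of its 4 probe sets in that direction. Of these 4, 1 passed over all probe sets. It was not the one that stood for the gene, and its direction is not given here. FST, the activin antagonist follistatin, had 0.64 ± 0.29 SE (adjusted p = 0.61; 0.0912 with the block). Thus, by the probe set that stood for each gene, 1 of the 4 measured genes fell and 3 did not pass. Adjusted over the list alone 3 were lower and 1 higher, which is not independent evidence either, and the list was called lower (adjusted p = 0.00702; adjusted p = 0.138 with an estimated correlation) with a mean of -0.26. That call was lost with the mean of a gene's probe sets (-0.05, adjusted p = 0.0519) and without probe sets that can match several transcripts (-0.06, adjusted p = 0.253), and the mean was negative in 3 of the 4 pairs.

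**Figure D3:**
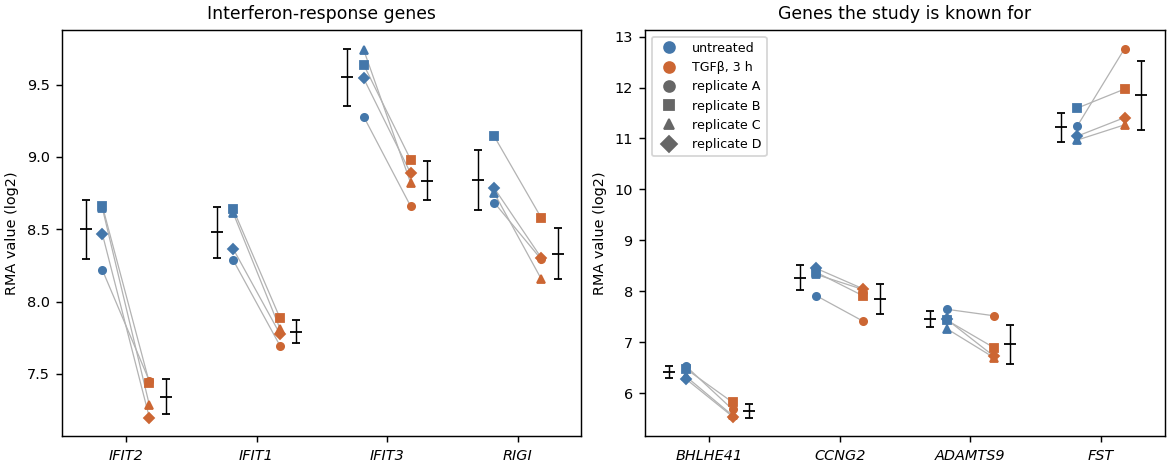
RMA log2 signal per array for 4 interferon-response genes and for the 4 measured genes for which the study is known. Grey lines join arrays of the same letter, and black bars are means with SD (n = 4 in each group); all 4 lines slope down for each gene except FST, where all 4 slope up.

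Some calls of named genes depended on the probe set that stood for the gene. With the mean of a gene's probe sets 16 of the 122 named genes lost their call. Besides BHLHE41 these were PTCH1 (-0.27, adjusted p = 0.193), ERBB3 (-0.38, adjusted p = 0.28), RUNX2 (-0.07, adjusted p = 0.841), PARD6B (-0.41, adjusted p = 0.162), RHOB (0.38, adjusted p = 0.151), CDH1 (0.48, adjusted p = 0.149), HBEGF (0.59, adjusted p = 0.0802) and FZD7 (-0.55, adjusted p = 0.251). PMEPA1, LGALSL, COL4A1, CSF1, FOSL2, IFIT3 and SPRED2 had adjusted p of 0.0844, 0.0686, 0.0514, 0.107, 0.0658, 0.0912 and 0.0831 there. Without probe sets that can match several transcripts only 99 of the 122 named genes had a value. Of these 5 lost it, BHLHE41, TPM1 (0.49, adjusted p = 0.275), GADD45B (0.30, adjusted p = 0.504), PDGFB (0.40, adjusted p = 0.355) and RUNX2 (adjusted p = 0.0529). RUNX2 and FZD7 also lost it with quantile normalization again (adjusted p = 0.0527 and 0.0552) and with a trended and robust prior (0.0678 and 0.0554). DUSP4 passed with the mean of its probe sets (adjusted p = 0.0246) and with that prior (0.0438), and THBS1 without probe sets that can match several transcripts (0.0159).

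Correlations between arrays lay between 0.986 and 0.996, and no arrays were identical. Treated replicate A stood apart in the control probe sets that compare the 3-prime with the 5-prime end of a transcript. Its 3-prime excess was 1.68 for ACTB (log2; 0.63 to 0.89 on the other arrays) and 0.54 for GAPDH (0.06 to 0.14 on the others). For the bacterial poly-A spikes added before labelling it was 2.36 (1.35 to 1.60 on the others). As means over 4 arrays the groups did not differ in any of these (exact permutation tests, two-sided, p = 0.743, 0.714 and 0.943; 70 arrangements). The probe sets for 28S ribosomal RNA were at 9.18 ± 0.76 in treated and 8.44 ± 0.22 in untreated arrays (SD, n = 4; exact permutation p = 0.0571, where 0.0286 is the smallest p possible). This test ignores the letters, and the treated array had the higher 28S value in 4 of 4 same-letter pairs. Treated replicate A had the highest value, 10.29. For 18S the same permutation test gave p = 0.171, and letter D went the other way (6.15 treated, 6.22 untreated).

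**Figure D4:**
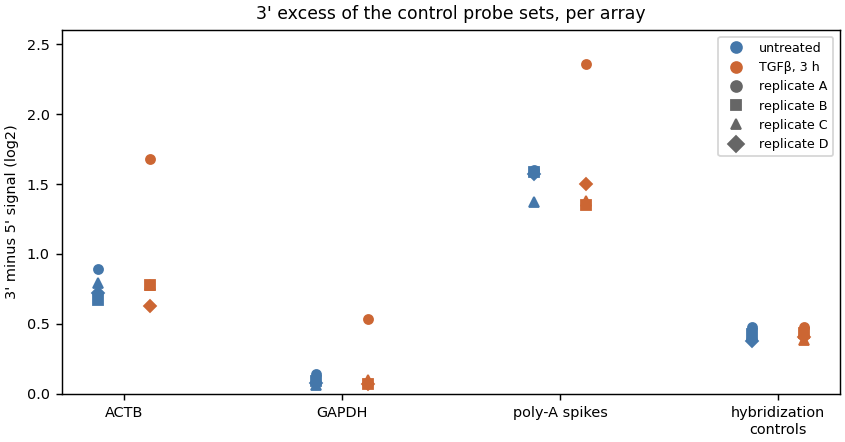
Difference between the 3-prime and 5-prime control probe sets (log2) on each of the 8 arrays for ACTB, GAPDH, the poly-A spikes and the hybridization controls. Treated replicate A lies above all others for the first 3 (1.68, 0.54 and 2.36) and within 0.38 to 0.48, as the others do, for the hybridization controls.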

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

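Tests of the 3-prime excess and of the shared deviations of same-letter arrays were chosen after these were seen. The other tests in this part were planned before their results, except the block fit without letter A. A value far from its group's other 3 arrays was found in 30 of 332 groups examined, where chance gives about 16.6; 12 of the 30 lie on treated replicate A.

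Treated replicate A had the 3-prime excess described for ACTB (1.68; 0.63 to 0.78 on the other treated arrays), GAPDH (0.54; 0.07 to 0.10) and the poly-A spikes (2.36, with 1.60 as the highest of the other 7). Degradation of the cells' RNA alone is argued against by the spikes, which were not in the cells: their excess on this array lay 0.76 above the highest of the other 7 arrays, whose SD was 0.11. An effect of TGFβ is argued against too, since the treated array of a letter other than A had as little as -0.10 relative to its untreated partner for ACTB. A shorter product of the labelling reaction may be the cause, since the hybridization controls, added after labelling, showed 0.48, beside 0.38 to 0.48 elsewhere. The biological explanation that the design offers is the effect of TGFβ already named.

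With the letter as a replicate block 705 genes passed in place of 114. Leaving out treated replicate A without a block gave 232 genes and not 705. That fit has fewer arrays, and leaving out any other single array gave only 46 to 96 genes. By itself it therefore cannot decide whether extra spread from treated replicate A is the whole cause. In a fit added after seeing the data, both arrays of letter A were left out and the block gave 1304 genes. More genes than 232 thus passed with the block also in the absence of treated replicate A. This argues against its extra spread as the whole cause, though no fit without the block left out both arrays. Shared deviations of same-letter arrays, with a lowest correlation of 0.30, are consistent with a larger count. In simulated data with shared letter effects the block raised the calls from 132 to 141. Only 200 genes were changed there, which left no room for a gain as large as the real one. The simulation therefore cannot decide whether shared letter effects account for the size of the gain. That size stays open, as does what the letters stand for. No biological explanation was tested.

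The list of interferon-response genes was called lower after TGFβ. The 3-prime bias of treated replicate A is argued against, as the list mean was -0.20 without that array and -0.23 with it. A single pair did not carry the difference, which stayed at -0.21 without the pair that moved it most. Of 10000 random lists of genes with similar signal, 0 percent had a mean as low, so a shift shared by genes of like signal does not account for it. An effect of TGFβ at 3 h on these genes may therefore be the source, as a hypothesis found and tested on the same arrays; camera with an estimated correlation did not call the list.

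Other splits of the arrays were refitted beside each count. Of 35 splits, 2 gave as many genes as the real 114, so chance is not excluded for that count: dividing the arrays into letters A and B against C and D gave the highest other value, 192, which points to a structure of the arrays by letter. For genes changed at least 1.5-fold, 1 split, the real one, gave 112, and the highest other gave 111. For probe sets 1 split, again the real one, gave 140, with 56 as the highest other. These shares, 1 of 35, would exclude chance only if all arrays could be exchanged, which the shared deviations of same-letter arrays speak against, so chance is not taken as excluded for either. For the lists 2 splits gave 14 or more, the highest other 15 (untreated A, C and D with treated D against the rest), and chance is not excluded. Among the 8 splits that part all 4 letters, as the real one does, the highest other values were 0 genes, 0 probe sets and 6 lists, and 8 splits are too few for a share under 0.05. The remaining splits put both arrays of a letter on 1 side.

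Further values lay far from the other 3 arrays of their group. On treated replicate A these were ANGPTL4 (11.03; others 10.17 to 10.27), RASGRP1 (3.66; 5.08 to 5.35), SMAD7 (7.28; 7.90 to 7.99), PLAU (10.86; 11.84 to 11.96), IL11 (10.54; 8.88 to 9.16), NR4A2 (6.62; 6.04 to 6.11), PECAM1 (6.89; 7.22 to 7.27), WNT7B (7.13; 6.55 to 6.61) and TGFBR3 (7.19; 5.79 to 5.99). On treated replicate B they were CCN2 (11.86), SQLE (9.66) and COL27A1 (7.25), and the list means of FOXO and starvation targets (7.65), mitosis (8.19), integrins and adhesion (8.73) and DNA replication (7.74). On treated replicate C it was PTCH1 (4.61; others 5.19 to 5.25). Among untreated arrays, replicate A stood apart for PTCH1 (6.13), IL11 (8.96) and LSS (10.18). Untreated replicate B did so for VGLL3 (6.13), COL4A1 (10.09), ID4 (6.21), NFKB1 (7.74) and the list means of mitosis (8.33) and ID genes (5.43), and untreated replicate C for the poly-A spikes (1.37).

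Probe sets for ribosomal RNA, which enter no comparison of genes, were above every untreated array on some treated arrays. For 28S they were at 10.29 on treated replicate A, 9.05 on treated replicate B and 8.75 on treated replicate D, with a highest untreated value of 8.68. For 18S they were at 7.58 on treated replicate A and 7.02 on treated replicate B, with a highest untreated value of 6.22.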

How the results depend on the processing

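The block fits without a letter, and camera with an estimated correlation in the block fit, were chosen after seeing the data. Under centring, quantile normalization again, the filter on signal and the other prior, the counts of genes, genes changed at least 1.5-fold, probe sets, lists and candidate genes stayed within 1.5 times the reported ones. The replicate block gave 705 genes, 313 changed at least 1.5-fold, 954 probe sets and 3 of the 4 candidate genes; beyond 34 named genes and the lung metastasis list it changed no call among named genes and lists. Without letter A, B, C or D the block fit gave 1304, 288, 321 and 356 genes. The mean of a gene's probe sets gave 74 genes changed at least 1.5-fold and 0 candidate genes, and leaving out probe sets that can match several transcripts also gave 0 candidate genes. Of the 14 lists called, 0 passed with an estimated correlation, with or without the block, and by fry 7 of the 14 and 1 other passed, 8 in all. Leaving out 1 array gave 46 to 232 genes, 46 to 208 changed at least 1.5-fold, 33 to 240 probe sets, 9 to 17 lists and 1 to 2 candidate genes; fewer arrays are part of this. The cause of the other differences was not tested.

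Signs changed mainly for lists near 0 that were not called. With the filter on signal the means were -0.0087 for clock genes and -0.013 for epithelial genes. With quantile normalization again they were 0.0019 for housekeeping, 0.009996 for NF-κB and 0.020 for the unfolded protein response. With the mean of probe sets they were -0.0031 for epithelial genes, 0.0059 for p63 targets and 0.017 for ribosomal proteins. Without probe sets that can match several transcripts they were -0.046 for clock genes, -0.010 for epithelial genes, -0.0089 for hypoxia, 0.0095 for p63 targets and 0.036 for ribosomal proteins. There the gene CASP8 had 0.24 against -0.20 in the reported fit. FAS had 0.069 against -0.65, a decrease that passed with the block (limma adjusted p = 0.0101). Leaving out 1 array moved the mean over -0.046 to 0.033 for housekeeping, -0.23 to 0.12 for NF-κB, -0.054 to 0.030 for the unfolded protein response, -0.054 to 0.18 for ID genes, -0.079 to 0.027 for p63 targets, -0.082 to 0.0099 for TGFβ ligands and receptors, -0.020 to 0.015 for ribosomal proteins, -0.0022 to 0.060 for epithelial genes and -0.0038 to 0.042 for clock genes. The DNA replication list, the only one of these that was called, ranged from -0.24 to 0.034. Signal over background, which RMA does not report, limits what can be said of genes of low signal such as CDH1 and RASGRP1.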

Other observations

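All tests of gene families in this part were chosen after the values had been seen. Of 9 measured frizzled receptors, the receptors for Wnt ligands, 3 fell and none rose. FZD1 had a log2 fold change of -0.97 ± 0.17 SE (adjusted p = 0.0348), FZD5 -0.92 ± 0.17 SE (adjusted p = 0.0471; 1 of its 2 probe sets in that direction) and FZD7 -0.66 ± 0.12 SE (adjusted p = 0.0422), each lower in 4 of 4 same-letter pairs. Each passed in only 2 of the 8 fits without 1 array, with adjusted p up to 0.146, 0.184 and 0.175 without untreated replicate C. The family mean was -0.37, and -0.40 to -0.34 with 1 array left out. The family may shift together: camera gave an adjusted p of 4.39e-05 over 4 families (adjusted p = 0.0238 with an estimated correlation). The 6 members that did not pass had a mean of -0.12, with 4 below 0, so most of the summed change lies in 3 receptors. Passing itself selects large changes, so this split cannot tell whether the whole family shifts. A shift of the family remains a hypothesis found and tested on the same arrays.

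Of 7 hedgehog pathway genes PTCH1 fell, and with the block HHIP, a hedgehog-binding protein, also rose (0.52 ± 0.31 SE, adjusted p = 0.775; 0.0198 with the block; camera adjusted p = 0.805). Of 16 nuclear receptors NR3C2 fell, and with the block 3 rose and 3 fell (camera adjusted p = 0.511). Neither family shifted as a whole in this test. The vitamin D receptor VDR had 1.02 ± 0.30 SE (adjusted p = 0.268; 0.00111 with the block).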
